A study of Homo sapiens with 12 samples.

How the data were processed

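Gene expression was measured with Illumina bead arrays in 2 human urothelial (bladder) cancer cell lines, UM-UC9 and UM-UC14. Per the labels, total RNA was copied to biotin-labelled cRNA and hybridized, 1 RNA sample to each of 12 arrays. UM-UC9 cells were untreated or given rosiglitazone, a drug that activates the nuclear receptor PPARG, at 1 µM for 24 hours. UM-UC14 cells carried a non-targeting short hairpin RNA (shRNA) or an shRNA against FABP4. Each of the 4 groups held 3 arrays, numbered as replicates 1 to 3, and whether these were separate cultures or repeats of 1 culture is not given in the sources used here. The p-values therefore measure only the spread between samples that may be technical repeats. The number of arrays limits the precision.

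The raw table deposited by the authors gave the intensity of each of 47323 probes on each array, as mean bead brightness on a linear scale without background subtraction or scaling between arrays. The scanner software and its filters are not given in the sources used here. The deposited raw values came with a detection p-value per probe and array, in steps set by 770 negative control probes, which is the share of those controls at least as bright as the probe. The authors also deposited processed values, which were log2 intensity with quantile normalization across the 12 arrays. This was checked on the values: the 12 columns held the same sorted values within 0.001, and they differed from quantile-normalized log2 raw intensity by 0.0106 at most. The values from the raw table were used for every comparison, because the processed values carry no background subtraction, and the processed values served as an alternative.

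Intensities were background corrected with limma's neqc function, which fits the normexp model to background estimated here from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Quantile normalization gives every array the same distribution, so that a shift of all genes in 1 direction cannot be seen. Background correction spreads dim probes over a wider range of log2 values. Probes with a detection p below 0.05 on at least 3 of the 12 arrays were kept, 25176 in all. Gene names came from the array annotation, which listed 1 gene for 30113 probes, several genes for 8 and none for 17202. The gene IDs of 30074 of the 30113 probes matched the reference of human genes (GRCh38.p14), used for names alone. Of the kept probes, 18384 named 1 gene, and each of 13293 genes was represented by the kept probe with the highest mean over all arrays. More than 1 kept probe was available for 3816 of these genes. No build is named with the array files, and no coordinates are given.

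One linear model with a mean per group was fitted to the 12 arrays with limma (lmFit and eBayes), which left 8 residual degrees of freedom, and 5.43 prior degrees of freedom were estimated. The contrasts were rosiglitazone minus control in UM-UC9, FABP4 shRNA minus non-targeting shRNA in UM-UC14, the difference between those changes, and the control groups of the cell lines (UM-UC14 with non-targeting shRNA minus untreated UM-UC9). A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05, and for the contrast of the cell lines also by a fold of at least 2. Standard errors (SE) are those of the model, and standard deviations (SD) are those of 3 arrays. A fold against a group in which the gene was detected on none of the arrays is given as a lower bound, computed against the detection limit of those arrays.

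Before the data were examined, 27 gene lists with 799 genes in all were written, the comparisons and most alternatives were set, and the rule for naming genes was fixed. The lists covered lipid metabolism (PPARG target genes, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, the fatty acid binding and uptake family), urothelial state (luminal differentiation, basal, epithelial junction and adhesion, mesenchymal and EMT, metalloproteinases and invasion proteases), the cell cycle (S phase, G2 and M phase, p53 target genes), inflammation (interferon response, NF-kB and inflammatory mediators), and stress (unfolded protein and ATF4 response, hypoxia and glycolysis, NRF2 oxidative stress, apoptosis and survival). Further lists covered FGFR and ERK output, TGF-beta response, MYC and ribosome biogenesis, oxidative phosphorylation, and retinoid, xenobiotic and steroid metabolism. The last 3 held markers of other cell types: fibroblasts, blood and endothelial cells, and adipocytes. Of the list genes, 666 were tested, 49 had no named probe, and 21 were renamed through synonyms. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a contrast. Camera with a correlation estimated from the data and fry, a rotation test of a list by itself, were run beside it.

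Genes were named by rule. FABP4 and PPARG were always named. In each treatment contrast the rule took the 6 largest rises and the 6 largest falls among genes that passed, whose 3 treated and 3 control values did not overlap, and that were detected on all 3 arrays of at least 1 group. It added up to 3 members with the smallest adjusted p from the PPARG target list, the luminal list and the 5 other lists with the smallest camera p. Across both contrasts it took up to 6 genes with opposite and up to 4 with the same direction, ranked by the smaller of their 2 absolute fold changes. For the cell lines it took the 5 largest each way and up to 3 members of 5 lists. Y-linked genes, XIST and clone names were left out. Other genes are named only where the text says that they were chosen after their values were seen.

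Pearson's r and Spearman's rho between the fold changes of the treatment contrasts were computed across genes, which are not independent replicates, with a two-sided permutation of labels within each cell line (10 by 10 splits). The model was tested on simulated data with 13293 genes and 50 changed genes of each size. At a log2 change of 0.5, it recovered 46% for rosiglitazone, 38% for FABP4 shRNA, 6% for the difference between them and 54% for the cell lines. At a log2 change of 1 these shares were 90%, 92%, 70% and 94%. The calls held 4 false ones of 125, 9 of 129, 6 of 94 and 4 of 132, in the same order. The simulation changed far fewer genes than were called in the real data, and it gave every group the same spread. These shares therefore need not hold for the real comparisons.

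Alternatives were quantile normalization without background correction, the authors' values, median scaling after background correction, each cell line alone, no filter on dim probes, detection on all 12 arrays, the mean of all tested probes of a gene, eBayes with trend and robust settings, the replicate number as a block, arrayWeights, an adjusted p below 0.01, a fold of at least 2, and leaving out each array in turn. Non-targeting replicate 1 as the only UM-UC14 control was added after the data had been seen. The computations used R 4.3.3 with limma 3.58.1 and the package data.table (1.17.8), and the plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.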

Results

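Expression profiles were obtained from 12 arrays, 3 in each of 4 groups: untreated UM-UC9 cells, UM-UC9 cells given rosiglitazone, UM-UC14 cells with non-targeting shRNA and UM-UC14 cells with FABP4 shRNA. Between 20892 and 22407 of the 47323 probes were detected on an array (44.1% to 47.3%). The median raw intensity of an array lay between 52.8 and 62.6. Arrays of the same group correlated at r of 0.984 to 0.997 across the tested genes, after normalization, in the 12 possible pairs. The study set cells in which FABP4 was modulated, by the drug or by knockdown, against their controls.

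FABP4, a cytoplasmic fatty acid carrier and a known target gene of PPARG, rose under rosiglitazone in UM-UC9 and fell with FABP4 shRNA in UM-UC14. Its probe (ILMN_1773006, the 1 probe for this gene) was detected on all 12 arrays. In UM-UC9 the normalized log2 intensity was 10.96 ± 0.13 in controls and 14.66 ± 0.05 with rosiglitazone (SD, n = 3 each), a log2 fold change of 3.69 (SE 0.11, adjusted p = 7.7e-11). In UM-UC14 it was 14.04 ± 0.10 with non-targeting shRNA and 10.33 ± 0.19 with FABP4 shRNA, a log2 fold change of -3.71 (SE 0.11, adjusted p = 2.9e-10). FABP4 thus stood 3.08 log2 units higher in UM-UC14 with non-targeting shRNA than in untreated UM-UC9 (adjusted p = 8.8e-12). PPARG, the receptor that rosiglitazone binds, fell in treated UM-UC9 cells from 14.71 ± 0.06 to 14.25 ± 0.03, a log2 fold change of -0.46 (SE 0.11, adjusted p = 0.0065). The log2 fold changes of its 3 other kept probes were -0.71, -1.07 and -1.20. Its log2 fold change with FABP4 shRNA was -0.21 (adjusted p = 0.20). Without non-targeting replicate 1 that value was -0.34 (adjusted p = 0.011).

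**Figure D1:**
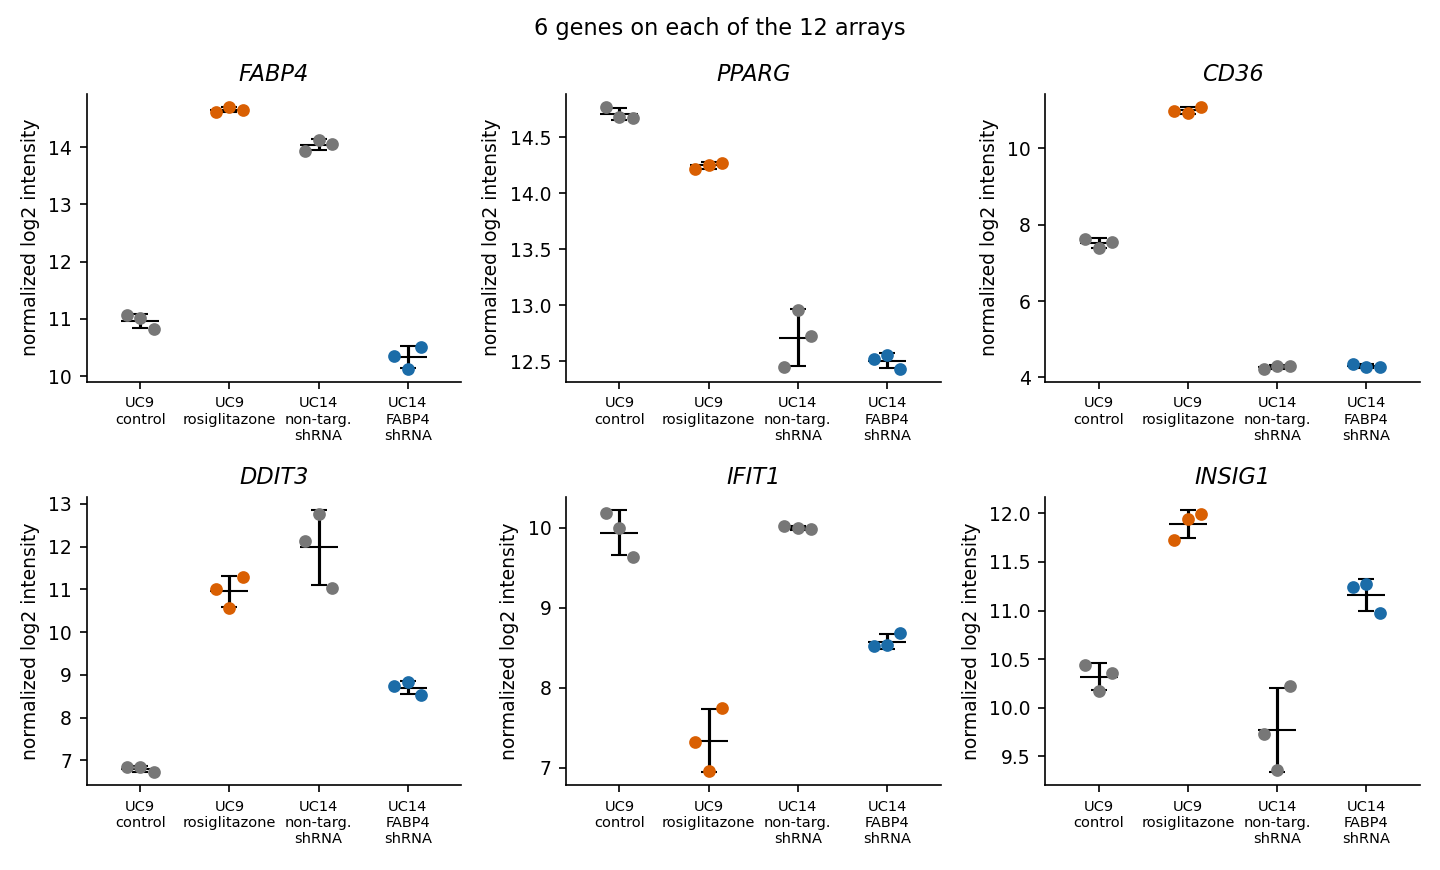
Normalized log2 intensity of FABP4, PPARG, CD36, DDIT3, IFIT1 and INSIG1 on each array (points; axes do not start at 0), with the mean (line) and SD (bars) of the 3 arrays per group, in UM-UC9 (UC9) controls and rosiglitazone-treated cells and in UM-UC14 (UC14) cells with non-targeting (non-targ.) or FABP4 shRNA. FABP4 means were 10.96, 14.66, 14.04 and 10.33 from left to right, DDIT3 was higher with rosiglitazone and lower with FABP4 shRNA than in its controls, and IFIT1 was lower in both.

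Rosiglitazone raised PPARG target, fatty acid oxidation, cholesterol and NRF2 genes in UM-UC9 and lowered interferon response genes and the cytokine IL11. The largest rises were in the flavin monooxygenase pseudogene FMO9P (log2 fold change 4.29, SE 0.16), the stress transcription factor DDIT3 (4.16, SE 0.31), the adaptor protein gene FYB1 (4.09), BBOX1, which encodes the last enzyme of carnitine synthesis (3.71), FABP4, and HPGD, which encodes a prostaglandin-degrading enzyme (3.50). The largest falls were in the oxysterol-binding protein gene OSBP2 (-4.08, SE 0.09), IL11 (-3.64), the cornified envelope gene SPRR2D (-3.53), the interferon-induced genes OAS2 (-3.45) and IFI44L (-3.41), and the transglutaminase TGM2 (-3.21).

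PPARG target genes rose as a group under rosiglitazone. Of 25 tested, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with a median log2 fold change of 0.50 and adjusted p = 4.1e-07. Besides FABP4 they included the fatty acid transporter CD36 (3.48, SE 0.09) and the lipid droplet coat protein PLIN2 (1.64). The member that fell was TXNIP, an inhibitor of thioredoxin and glucose uptake, at -2.67, named after its value was seen. Fatty acid oxidation had 21 of 28 genes higher and none lower, the same numbers adjusted over the list alone (median 0.65, adjusted p = 1.0e-11). Its examples were the acyl-CoA thioesterases ACOT2 (1.41) and ACOT1 (0.96) and the reductase DECR1 (1.10). In cholesterol synthesis and uptake 13 of 18 genes rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 4.9e-05). TM7SF2 and MSMO1, enzymes of sterol synthesis, rose by 1.48 and 0.91 log2 units, and the sterol sensor INSIG1 by 1.57. NRF2 oxidative stress genes, which serve glutathione and detoxification, rose in 16 of 27 and fell in 2 (16 and 3 adjusted over the list alone; adjusted p = 1.2e-04). These 4 calls and that of the interferon list also passed with an estimated correlation, at adjusted p between 0.013 and 0.037. In fatty acid and triglyceride synthesis 6 of 23 genes rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0057, and adjusted p = 0.18 with an estimated correlation).

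Interferon response genes, which are induced in antiviral defence, fell in 26 of 41 cases under rosiglitazone and rose in 3 (28 and 3 adjusted over the list alone). Their median log2 fold change was -0.97 (adjusted p = 1.2e-10), with IFI44 at -2.51. MYC and ribosome biogenesis genes fell in 26 of 32 cases and rose in 0 (28 and 0 adjusted over the list alone; adjusted p = 8.4e-09, and adjusted p = 0.31 with an estimated correlation). The RNA polymerase I subunit POLR1B had a log2 fold change of -1.07, and the ribosome assembly factors TSR1 and NOP16 had -0.996 and -0.98. NF-kB and inflammatory mediators fell in 14 of 31 cases and rose in 3 (the same adjusted over the list alone; adjusted p = 0.0048, and adjusted p = 0.24 with an estimated correlation). Apoptosis and survival genes fell in 9 of 29 cases and rose in 1 (the same adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.18 with an estimated correlation).

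G2 and M phase genes rose in 25 of 41 cases and fell in 1 (26 and 1 adjusted over the list alone; adjusted p = 3.9e-07, and adjusted p = 0.060 with an estimated correlation), among them the mitotic phosphatase CDC25C (0.90) and the centromere proteins CENPA (0.79) and CENPF (0.62). S phase genes fell in 18 of 38 cases and rose in 3 (19 and 4 adjusted over the list alone; adjusted p = 0.0066, and adjusted p = 0.47 with an estimated correlation). Luminal differentiation genes, which mark the surface layers of the urothelium, rose in 15 of 31 cases and fell in 5 (16 and 6 adjusted over the list alone; adjusted p = 0.0017, and adjusted p = 0.32 with an estimated correlation). The umbrella cell keratin KRT20 rose by 1.73 log2 units, the uroplakin UPK1B by 1.42 and the ubiquitin ligase TRIM31, detected on 2 of 3 control arrays, by 1.26. Hypoxia and glycolysis genes rose in 18 of 34 cases and fell in 4, and unfolded protein and ATF4 response genes rose in 17 of 33 and fell in 1 (18 and 4, and 17 and 2, adjusted over the list alone). Both had an adjusted p = 0.0013, and adjusted p = 0.50 with an estimated correlation. Oxidative phosphorylation genes rose in 14 of 45 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.0037, and adjusted p = 0.24 with an estimated correlation). Adipocyte markers rose in 3 of 7 cases and fell in 1 (the same adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.24 with an estimated correlation), and 4 of the 7 also belong to the PPARG target list.

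The other 11 lists did not pass under rosiglitazone. Their adjusted p-values were 0.080 for retinoid, xenobiotic and steroid metabolism (11 of 31 rose, 6 fell), 0.13 for FGFR and ERK output (6 of 29 rose, 9 fell), 0.14 for blood and endothelial markers (4 of 12 rose, 2 fell) and 0.29 for TGF-beta response (3 of 24 rose, 8 fell). For fibroblast markers (2 of 8 rose, 0 fell) the value was 0.33, and for the fatty acid binding and uptake family (3 of 11 rose, 0 fell) it was 0.34. Basal markers had 0.49 (5 of 19 rose, 6 fell), epithelial junction and adhesion 0.55 (3 of 23 rose, 4 fell), mesenchymal and EMT 0.79 (1 of 20 rose, 4 fell), metalloproteinases and invasion proteases 0.84 (3 of 25 rose, 6 fell) and p53 target genes 0.99 (6 of 22 rose, 5 fell). Adjusted over the list alone, FGFR and ERK output had 6 higher and 13 lower, basal markers 6 and 8, epithelial junction 3 and 3, mesenchymal 1 and 3, and the other 7 lists kept their numbers. The median of the fatty acid binding family was -0.15 while its mean was 0.58 and its test pointed up. The mesenchymal median was 0.03 with a mean of -0.11 and a test pointing down, and for metalloproteinases and p53 target genes the means of 0.01 and 0.03 were positive while the median and the test were negative.

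In all, 4789 of 13293 genes changed with rosiglitazone (36.0%), 2259 upward (47.2%) and 2530 downward. With median scaling in place of quantile normalization the upward share was 40.01%. A change of at least 2-fold was seen in 539 of them, 316 upward and 223 downward. The 3 treated and 3 control arrays did not overlap for 53.9% of all tested genes, where chance gives 10%.

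With FABP4 shRNA in UM-UC14, cholesterol genes rose and hypoxia, interferon and unfolded protein response genes fell. With an estimated correlation the falls did not pass (adjusted p = 0.30, 0.072 and 0.32). How many shRNA sequences were used against FABP4 is not given in the sources used here. Effects of the shRNA that are separate from FABP4 therefore cannot be told apart from those of lower FABP4. Besides FABP4, the largest falls were in the stress cytokine GDF15 (log2 fold change -3.99, SE 0.24), the iron-siderophore carrier LCN2 (-3.40, SE 0.12), DDIT3 (-3.28, SE 0.31), CLCA4, of the calcium-activated chloride channel regulator family (-2.95), and the receptor for oxidised LDL, OLR1 (-2.94). The largest rises were in the calcium-binding protein S100A8 (2.59, SE 0.20), the calmodulin-like gene CALML3 (2.44), KRT14 (2.03), BEGAIN (1.87), the lipase LIPG (1.78) and KRT5. CALML3 and KRT14 were each detected on 1 of 3 non-targeting arrays, so that the size of their rise is not exact, and KRT5 on 0 of 3, so that KRT5 was at least 2.83-fold higher with FABP4 shRNA.

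Non-targeting replicate 1 stood apart from replicates 2 and 3: across genes it correlated at r = 0.989 with the mean of the FABP4 shRNA arrays and at 0.988 with that of the other non-targeting arrays. Lists that lost their call with this array as the only control, an alternative added after the data had been seen, are given below with that adjusted p. The spread in that fit comes from the other groups, and the lone array is assumed to vary as they do. Without it 5238 genes changed, and with it as the only control 1940 changed, of which 1310 changed in the same direction against all controls.

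Hypoxia and glycolysis genes fell in 20 of 34 cases with FABP4 shRNA and rose in 0 (23 and 0 adjusted over the list alone), with a median of -0.53 (adjusted p = 1.6e-10, and adjusted p = 0.30 with an estimated correlation). Examples were the lipid droplet protein HILPDA (-2.47), MXI1, an antagonist of MYC (-1.72), and NDRG1 (-1.81). Interferon response genes fell in 23 of 41 cases and rose in 0 (24 and 0 adjusted over the list alone), with a median of -0.44 (adjusted p = 3.8e-09, and adjusted p = 0.072 with an estimated correlation), including HERC5 (-2.04), OASL (-1.62) and IFIT2 (-1.79). Unfolded protein and ATF4 response genes fell in 11 of 33 cases and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 7.3e-07, and adjusted p = 0.32 with an estimated correlation). They included DDIT3, the phosphatase subunit PPP1R15A (-2.54) and the transcription factor ATF3 (-2.42). Non-targeting replicates 1 to 3 read 12.14, 12.77 and 11.04 for DDIT3, against 8.53 to 8.83 with the shRNA. For ATF3 they read 9.43, 9.57 and 8.37, against 6.62 to 6.76. TRIB3 and CHAC1 were chosen after their values were seen. TRIB3 read 11.35, 11.20 and 8.78, against 8.90 to 9.32, and CHAC1 6.22, 7.46 and 4.96, against 6.22 to 6.89. Replicate 3 was thus the lowest control for these genes. NF-kB and inflammatory mediators fell in 13 of 31 cases and rose in 2 (14 and 2 adjusted over the list alone; adjusted p = 2.6e-05, and adjusted p = 0.14 with an estimated correlation).

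Cholesterol synthesis and uptake genes rose in 12 of 18 cases with FABP4 shRNA and fell in 0, the same adjusted over the list alone (median 0.58, adjusted p = 2.0e-07), and this was the 1 call of this contrast that also passed with an estimated correlation (adjusted p = 0.047). The synthesis enzymes IDI1 and LSS rose by 1.02 and 1.24 log2 units, and INSIG1 by 1.39. Fatty acid and triglyceride synthesis genes rose in 14 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone; adjusted p = 5.6e-06, and adjusted p = 0.072 with an estimated correlation). MYC and ribosome biogenesis genes rose in 17 of 32 cases and fell in 0 (20 and 0 adjusted over the list alone; adjusted p = 1.0e-06, and adjusted p = 0.32 with an estimated correlation). The pyrimidine synthesis gene CAD rose by 0.81 log2 units, the cap-binding protein EIF4E by 0.65 and NOP16 by 0.56. With non-targeting replicate 1 as the only control, this list had an adjusted p of 0.22, and the log2 fold changes of CAD (0.29), EIF4E (0.52) and NOP16 (0.24) no longer passed (adjusted p = 0.17, 0.11 and 0.25). Oxidative phosphorylation genes rose in 15 of 45 cases and fell in 0 (the same adjusted over the list alone; adjusted p = 3.6e-04, and adjusted p = 0.28 with an estimated correlation). G2 and M phase genes rose in 9 of 41 cases and fell in 0 (the same adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.30 with an estimated correlation).

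Luminal differentiation genes fell in 12 of 31 cases with FABP4 shRNA and rose in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.32 with an estimated correlation). Examples were the claudin CLDN7 (-1.03), TRIM31 (-1.35) and VSIG2 (-1.27). Retinoid, xenobiotic and steroid metabolism genes fell in 12 of 31 cases and rose in 2 (12 and 3 adjusted over the list alone; adjusted p = 3.6e-04, and adjusted p = 0.33 with an estimated correlation). FGFR and ERK output genes fell in 10 of 29 cases and rose in 4 (12 and 5 adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.32 with an estimated correlation). Epithelial junction and adhesion genes fell in 10 of 23 cases and rose in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.30 with an estimated correlation). S phase genes rose in 8 of 38 cases and fell in 3 (the same adjusted over the list alone; adjusted p = 0.013, and adjusted p = 0.39 with an estimated correlation). With non-targeting replicate 1 as the only control the adjusted p was 0.37 for luminal, 0.63 for retinoid, 0.41 for FGFR, 0.32 for junction and 0.35 for S phase genes. In the same fit the retinoid median was 0.14 and the FGFR median 0.05, against -0.31 and -0.26 with all controls.

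The other 13 lists did not pass with FABP4 shRNA. PPARG target genes rose in 3 of 25 cases and fell in 6 (5 and 9 adjusted over the list alone; adjusted p = 0.079), and PLIN2 (-1.28) and HILPDA were among those that fell beside FABP4. This list passed with median scaling (adjusted p = 0.023) and among genes detected on all 12 arrays (adjusted p = 0.033), at medians of -0.0088 and -0.24. It holds FABP4, the gene that the shRNA targets, and was not tested without that gene. These passes therefore do not show that the other PPARG target genes fell as a group. For p53 target genes (2 of 22 rose, 4 fell) the adjusted p was 0.060, but the list passed without background correction (0.047), in the authors' values (0.047), among genes detected on all 12 arrays (0.019), with arrayWeights (0.037) and with non-targeting replicate 1 as the only control (0.013). The adjusted p was 0.071 for blood and endothelial markers (0 of 12 rose, 3 fell), 0.093 for adipocyte markers (0 of 7 rose, 2 fell) and 0.16 for fibroblast markers (4 of 8 rose, 1 fell). Adipocyte markers passed among genes detected on all 12 arrays (adjusted p = 0.049), and fibroblast markers with non-targeting replicate 1 as the only control (adjusted p = 0.048). It was 0.21 for TGF-beta response (5 of 24 rose, 9 fell), 0.27 for basal markers (5 of 19 rose, 3 fell), 0.28 for NRF2 oxidative stress (4 of 27 rose, 7 fell) and 0.34 for metalloproteinases (4 of 25 rose, 6 fell). For the fatty acid binding family it was 0.61 (2 of 11 rose, 2 fell), for fatty acid oxidation 0.72 (2 of 28 rose, 4 fell), for apoptosis and survival 0.88 (7 of 29 rose, 6 fell) and for mesenchymal and EMT 0.98 (4 of 20 rose, 5 fell). Adjusted over the list alone, TGF-beta response had 6 higher and 9 lower, basal markers 6 and 3, the fatty acid binding family 3 and 3, fatty acid oxidation 1 and 3, apoptosis 8 and 6, mesenchymal 5 and 5, and the other 6 lists kept theirs. The fatty acid binding family had a median of 0.12 with a mean of -0.28 and a test pointing down, and the mesenchymal list a median of -0.01 with a mean of 0.05 and a test pointing up. The apoptosis median was 0.00364 with a mean of -0.02 and a test pointing down.

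In all, 3502 of 13293 genes changed with FABP4 shRNA (26.3%), 1885 upward (53.8%) and 1617 downward, and 304 changed by at least 2-fold, 76 upward and 228 downward (525 without non-targeting replicate 1). The model shares 1 variance per gene among all groups, but the non-targeting arrays varied more. The SD across genes of the difference between 2 arrays was 0.28 to 0.43 there, against 0.19 to 0.20 with FABP4 shRNA. The shared variance may thus understate the error of this contrast, and UM-UC14 alone gave 1829 genes. With median scaling in place of quantile normalization the upward share was 69.98%. The groups did not overlap for 36.5% of all tested genes, where chance gives 10%.

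Rosiglitazone, which raised FABP4, and the shRNA, which lowered it, moved more shared genes in opposite directions than in the same one. Among 1547 genes that changed in both contrasts, 1190 (76.9%) went opposite ways. Of these, 530 rose with rosiglitazone and fell with the shRNA (275 if the contrasts were independent), and 660 did the reverse (359). The same direction was shared by 357 genes, 181 upward (320 if independent) and 176 downward (308). Of 75 genes changed at least 2-fold in both, 56 were opposite. Besides FABP4, the opposite genes included stress genes: GDF15 (3.33 with rosiglitazone, -3.99 with the shRNA), DDIT3 (4.16 and -3.28) and PPP1R15A (2.16 and -2.54). They also included TMEM140 (2.35 and -2.12) and the muscle atrophy ubiquitin ligase FBXO32 (2.05 and -2.89). The same direction was taken by KRT14 (1.61 and 2.03), the arginine deiminase PADI4 (2.78 and 1.46), IFIT1, an interferon-induced protein (-2.60 and -1.42), and INSIG1 (1.57 and 1.39). Of the cholesterol list 10 genes changed in both, all 10 in the same direction. Among lists that passed in both contrasts at the preset correlation, interferon and NF-kB lists fell in both. Cholesterol, fatty acid synthesis, oxidative phosphorylation and G2 and M phase lists rose in both. MYC, S phase, hypoxia, unfolded protein and luminal lists went opposite ways.

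**Figure D2:**
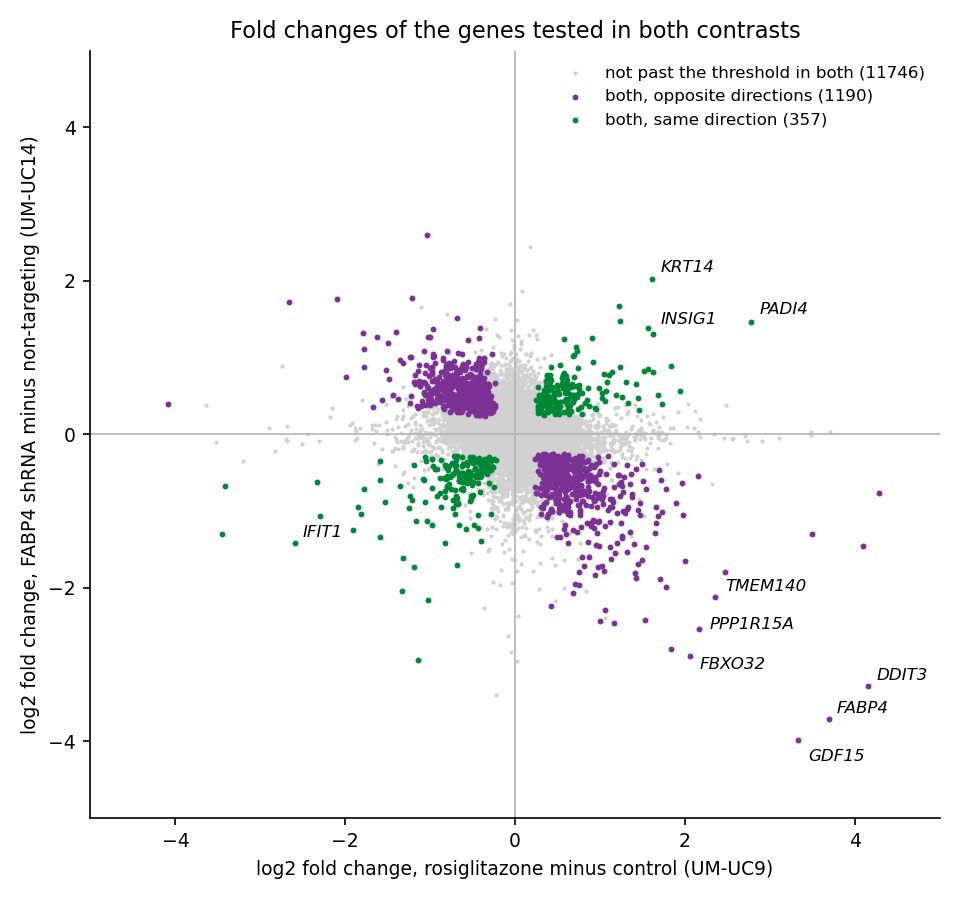
Log2 fold change of each of 13293 genes with rosiglitazone in UM-UC9 (horizontal) and with FABP4 shRNA in UM-UC14 (vertical); genes past adjusted p of 0.05 in both are coloured by whether their directions were opposite (1190) or the same (357). FABP4, DDIT3 and GDF15 lie far to the lower right, raised by the drug and lowered by the shRNA.

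Across the 13293 genes, which are not independent replicates, the fold changes of both contrasts correlated at Pearson's r = -0.274 and Spearman's rho = -0.291. Of 100 permutations of labels within the cell lines, the real one included, 20 gave an r as large in either direction (permutation p = 0.20, two-sided) and 16 such a rho (p = 0.16), where the smallest possible p is 0.01. Any other split leaves part of the treatment difference between its groups, and r takes no account of its size. The covariance does, and was chosen after r had been seen: it was -0.0506, against 0.0412 at most in size for the other permutations (1 of 100 as large). Since other splits shrink the fold changes and with them any covariance, this favours the real one by design and decides nothing. With non-targeting replicate 1 as the only control 617 of 1047 shared genes were opposite (58.9%), and r was -0.0993.

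The change itself differed between the contrasts for 5520 genes, 2539 with a higher and 2981 with a lower change under rosiglitazone than with the shRNA. Cell line and treatment differ together in this test. Among the lists 11 differed. MYC and ribosome biogenesis was lower under rosiglitazone for 28 of 32 genes (28 adjusted over the list alone; adjusted p = 6.3e-10, and adjusted p = 0.42 with an estimated correlation). Higher under rosiglitazone were hypoxia and glycolysis (23 of 34 genes; adjusted p = 1.3e-07), unfolded protein and ATF4 response (20 of 33; adjusted p = 1.1e-06), PPARG target genes (14 of 25; adjusted p = 2.1e-05), luminal differentiation (17 of 31; adjusted p = 1.8e-04) and retinoid metabolism (16 of 31; adjusted p = 0.0013). With an estimated correlation the adjusted p of these 5 lists was 0.46, 0.47, 0.10, 0.42 and 0.51. The PPARG target list holds FABP4, which the drug and the shRNA moved in opposite directions. Fatty acid oxidation (19 of 28 genes higher; adjusted p = 2.2e-07) and NRF2 oxidative stress (14 of 27 higher; adjusted p = 0.0011) also passed with an estimated correlation (adjusted p = 0.049 for both). S phase genes (19 of 38 lower; adjusted p = 0.0016, and adjusted p = 0.47 with an estimated correlation), the interferon response (19 of 41 lower, 9 higher; adjusted p = 0.048, and adjusted p = 0.47 with an estimated correlation) and adipocyte markers (3 of 7 higher; adjusted p = 0.0497, and adjusted p = 0.42 with an estimated correlation) made up the rest. The counts of genes in these directions were the same adjusted over the list alone. The interferon call did not hold with median scaling (adjusted p = 0.080), among genes detected on all 12 arrays (0.082) or with arrayWeights (0.12). With non-targeting replicate 1 as the only control the retinoid (median 0.18, adjusted p = 0.12) and adipocyte calls (adjusted p = 0.18) were lost, and apoptosis and blood and endothelial markers passed (adjusted p = 0.039 for both).

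**Figure D3:**
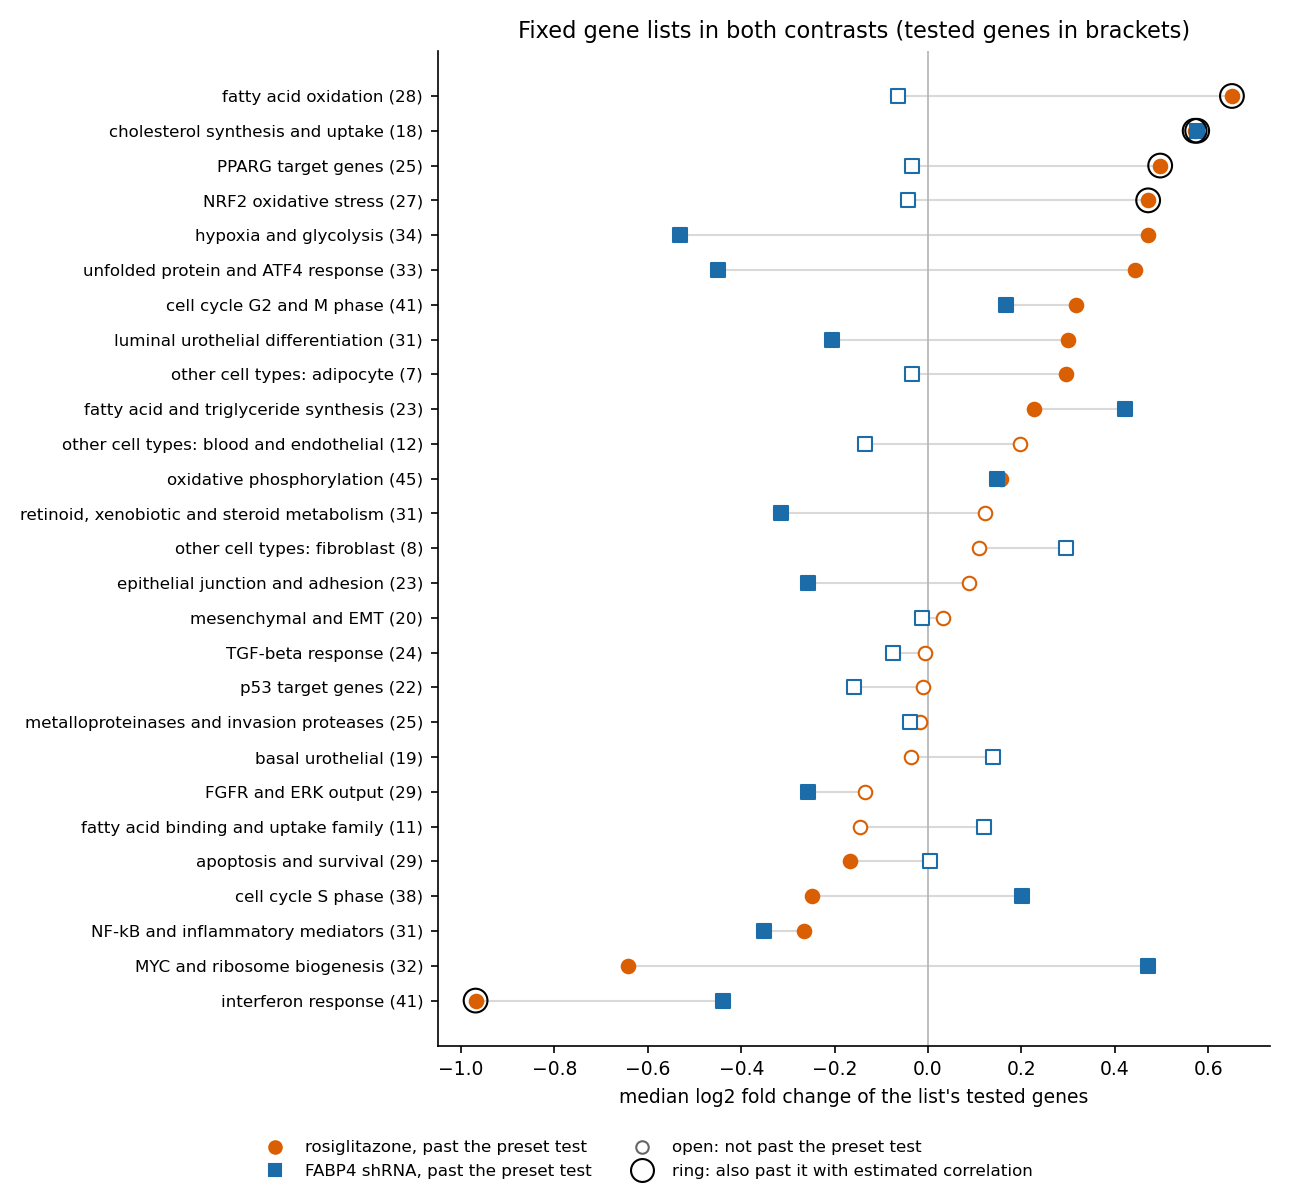
Median log2 fold change of each of the 27 gene lists (number of tested genes in brackets) with rosiglitazone (circles) and with FABP4 shRNA (squares); filled symbols passed camera with a preset correlation of 0.01 at an adjusted p below 0.05, and a black ring marks those that also passed with an estimated correlation. Interferon response was lower in both (-0.97 and -0.44), cholesterol synthesis higher in both, and hypoxia, unfolded protein response and MYC lists lay on opposite sides of 0.

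The untreated UM-UC9 cells and the UM-UC14 cells with non-targeting shRNA were compared to describe the starting state of the lines. UM-UC14 expressed the suprabasal keratin KRT13 far above UM-UC9 (normalized log2 intensity 14.15 ± 0.05 against 4.76 ± 0.10), as well as the glutathione enzymes GSTM1 (at least 508-fold higher), GSTM2 (14.09 ± 0.09 against 4.849 ± 0.25) and GPX2 (at least 474-fold), and the tetraspanin CD81 (at least 438-fold). KRT13 and GSTM2 were each detected on 1 of 3 UM-UC9 control arrays, so that no exact fold is given. UM-UC9 was higher in COXFA4L3, a relative of a cytochrome c oxidase subunit (UM-UC14 at least 518-fold lower), the retinoid-responsive gene RARRES1 (at least 307-fold lower), the gastric protein gene GKN1 (at least 195-fold lower), the cancer-testis antigen MAGEA10 (at least 136-fold lower) and the elongation factor EEF1A2 (at least 122-fold lower). PPARG was lower in UM-UC14 by a log2 fold change of -1.999 (adjusted p = 1.6e-09).

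Members of a list were counted as higher or lower by their adjusted p alone, without the fold threshold. Luminal genes were higher in UM-UC14 in 17 of 31 cases and lower in 8 (the same adjusted over the list alone; adjusted p = 0.039, and adjusted p = 0.79 with an estimated correlation), with the uroplakin UPK3B at 4.28, KRT13 and GPX2. This call did not hold among genes detected on all 12 arrays (adjusted p = 0.19) or with the mean of all probes of a gene (0.059). Of 19 basal genes 11 were higher and 7 lower (the same adjusted over the list alone; adjusted p = 0.64), among them P-cadherin, CDH3 (5.47), the desmosomal cadherin DSC2 (-5.39) and KRT6C (at least 9.30-fold lower in UM-UC14). Of 20 mesenchymal genes 13 were higher and 6 lower (the same adjusted over the list alone; adjusted p = 0.070, and 0.012 with median scaling), with the transcription factor SNAI2 at 4.51, the gelatinase MMP2 at least 3.78-fold higher and FSTL1 at least 4.98-fold lower. Of 25 PPARG target genes 6 were higher and 11 lower (the same adjusted over the list alone; adjusted p = 0.51), with IMPA2 at 3.00, and G0S2 and CD36 at least 6.65-fold and 6.43-fold lower. The fatty acid binding and uptake family had 4 of 11 higher, the transporter-family enzyme SLC27A3 (4.09) and FABP4 among them, and 3 lower (the same adjusted over the list alone; adjusted p = 0.70).

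Hypoxia and glycolysis genes were higher in UM-UC14 in 27 of 34 cases (adjusted p = 9.9e-05), unfolded protein and ATF4 response in 22 of 33 (adjusted p = 8.0e-04), G2 and M phase in 29 of 41 (adjusted p = 0.0013), NRF2 oxidative stress in 17 of 27 (adjusted p = 0.0014), retinoid metabolism in 19 of 31 (adjusted p = 0.0057) and fibroblast markers in 6 of 8 (adjusted p = 0.049). NF-kB mediators were lower in 21 of 31 cases (adjusted p = 1.0e-04) and MYC and ribosome biogenesis in 24 of 32 (adjusted p = 0.0027). With an estimated correlation these adjusted p-values were 0.73, 0.79, 0.33, 0.092, 0.79, 0.28, 0.28 and 0.79, in the same order. With no filter on dim probes the fibroblast median was 0.04 in place of 1.55 and its call was lost (adjusted p = 0.26). Adjusted over the list alone, the unfolded protein list had 23 higher and the counts of the other 7 lists stayed as given. In all, 3449 genes differed by at least 2-fold, 1724 higher and 1725 lower in UM-UC14. The groups did not overlap for 68.1% of all tested genes, where chance gives 10%. Cell line and the presence of an shRNA cannot be told apart in this comparison, and median scaling moved the median of all genes to -0.15 from -0.02. Of genes past the adjusted p alone, 49.0% were higher in UM-UC14, and 39.5% with median scaling.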

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

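The comparison of probes without a gene name with named probes was chosen only after their number had been seen. The array annotation lists no gene for 6792 of the probes that passed the detection filter, and the gene comparisons leave these out. They nevertheless responded to both treatments. With rosiglitazone 1292 of them changed, 606 upward and 686 downward, 141 by at least 2-fold. This was 19.02% of the probes without a name, against 32.3% of the named probes. The largest rise was in probe ILMN_1815203 (log2 fold change 5.40, SE 0.11), above that of any gene named for this contrast, and the largest fall in ILMN_3275206 (-3.08, SE 0.13). With FABP4 shRNA 1080 of them changed, 611 upward and 469 downward, 77 by at least 2-fold, or 15.9% against 23.5% of the named probes. The extremes were ILMN_2219002 (2.43, SE 0.13) and ILMN_1653278 (-2.37, SE 0.24). The files do not pair these probes with genes, and what they measure was not tested.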

How the results depend on the processing

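The fit with non-targeting replicate 1 as the only control was chosen after the data had been seen and assumes that this array varies as those of the other groups do. Over all alternatives 211 values that answer a comparison kept their direction and call, or for counts stayed within 1.5 times. Of values for single named genes 1454 kept both, 3 lost and 2 gained a call. Of list values 1910 kept both, while 95 lost a call and 65 gained one. A direction that turned without a call in either fit was counted as kept. The cause of the changes below was not tested, except that stricter thresholds lower counts by construction. An adjusted p below 0.01 gave 3032 genes for rosiglitazone, 1726 for FABP4 shRNA, 571 for both and 3567 for the difference, and a fold of at least 2 gave 539, 304, 75 and 1558; the cell line threshold already held that fold. Detection on all 12 arrays gave 2270 genes for the cell lines. UM-UC14 alone gave 1829 genes for FABP4 shRNA, and arrayWeights gave 2678 for both contrasts and made the PPARG change of -0.34 with FABP4 shRNA pass (adjusted p = 0.016). With an estimated correlation 5, 1, 2 and 0 lists passed for rosiglitazone, FABP4 shRNA, the difference and the cell lines, and fry called 23, 22, 20 and 20. Fry turned the direction of adipocyte markers between the cell lines (median -0.18, adjusted p = 0.024). Without a call in either test, it also turned FGFR and ERK output and NF-kB mediators in the difference. The same held for TGF-beta response and blood and endothelial markers between the cell lines. Median scaling ended the junction call with FABP4 shRNA (adjusted p = 0.071) and gave one to PPARG target genes (0.023), adipocyte (0.039) and blood markers (0.015) there, to retinoid metabolism under rosiglitazone (0.033) and to blood markers in the difference (0.012). No filter on dim probes ended the adipocyte calls under rosiglitazone (0.14) and in the difference (0.21) and gave one to G2 and M phase in the difference (0.046) and to junction genes between the cell lines (0.0495). The mean of all probes ended the apoptosis call under rosiglitazone (0.090) and gave one to junction genes in the difference (0.044). The adipocyte call in the difference also ended without background correction, in the authors' values (both 0.053), with detection on all 12 arrays (0.10) and with arrayWeights (0.054), and that under rosiglitazone with UM-UC9 alone (0.063). Detection on all 12 arrays ended the rosiglitazone calls of NF-kB (0.079), apoptosis (0.062) and adipocyte lists (0.11) and gave one to retinoid metabolism (0.0081). Non-targeting replicate 1 as the only control gave 1940 genes for FABP4 shRNA, an opposite share of 58.9% and r = -0.0993.

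Leaving out 1 array gave 3560 to 4242 genes for rosiglitazone, 2369 to 5238 for FABP4 shRNA, 3356 to 3705 for the cell lines, 4723 to 6754 for the difference and 1053 to 2741 for both, the last without non-targeting replicate 1. The opposite share was 75.6% to 79.3% with all arrays and 71.6% (without non-targeting replicate 3) to 78.8% (without non-targeting replicate 1) leaving out 1. Lists near the threshold turned on single arrays. Under rosiglitazone, adipocyte markers lost their call without control replicate 1 (adjusted p = 0.063) or any rosiglitazone array (0.32, 0.18 and 0.13), apoptosis without control replicate 1 (0.052) or rosiglitazone replicate 2 (0.077), and retinoid metabolism passed without rosiglitazone replicate 2 (0.047). With FABP4 shRNA, S phase and junction lists lost theirs without non-targeting replicate 3 (both 0.051), where p53 target genes passed (0.0071), and blood markers passed without non-targeting replicate 2 (0.038). Between the cell lines, luminal genes lost theirs without non-targeting replicate 2 (0.054) and fibroblast markers without control replicate 2 (0.055), and p53 target genes passed without non-targeting replicate 3 (0.048). In the difference, the interferon and adipocyte calls ended without control replicate 1 (0.053 and 0.075), rosiglitazone replicate 1 (0.061 and 0.27) and 2 (0.068 and 0.18), and non-targeting replicate 1 (0.14 and 0.060) and 3 (0.063 and 0.075). The interferon call also ended without control replicate 2 (0.052), and the adipocyte call without rosiglitazone replicate 3 (0.13), non-targeting replicate 2 (0.056) and FABP4 shRNA replicate 2 (0.056). Blood and endothelial markers passed there without control replicate 2 (0.020), rosiglitazone replicate 2 (0.045) or 3 (0.039), non-targeting replicate 2 (0.037), or FABP4 shRNA replicate 1 (0.040) or 3 (0.049).

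With the replicate number as a block, 4578 genes changed with rosiglitazone, 3247 with FABP4 shRNA and 1428 in both. The block ended the adipocyte call under rosiglitazone (adjusted p = 0.051) and the interferon (0.056) and adipocyte calls (0.069) in the difference, where blood and endothelial markers passed (0.046). The deviations of treated and control arrays of equal number from their group means hardly correlated across genes (r of -0.0356 to -0.00850 in UM-UC9 and 0.0177 to 0.147 in UM-UC14). Arrays of unequal number gave r of -0.0387 to 0.0651 in UM-UC9 and -0.12 to 0.067 in UM-UC14. Since paired samples need not share such deviations, this does not decide whether the numbers pair the samples. The signal over background limits what can be said of the probes not detected on an array, and the number of arrays limits small changes.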

Other observations

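Chosen only after the result was seen were the tests of mixing, of array quality and of FABP4 level as a driver of interferon genes, the fit with non-targeting replicate 1 as the only control, and the genes named in the next paragraph.

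As a list, NF-kB and inflammatory mediators did not pass in the difference between the contrasts (12 of 31 higher and 10 lower under rosiglitazone, 13 and 12 adjusted over the list alone; adjusted p = 0.81). The cystine transporter SLC7A11 rose with rosiglitazone (1.74) and fell with FABP4 shRNA (-1.01), as did GCLC, an enzyme of glutathione synthesis (0.53 and -0.97), and the changes differed between the contrasts (adjusted p = 2.5e-06 and 3.3e-05). Rosiglitazone lowered the cytokine IL6 (-2.83, adjusted p = 7.9e-09), whose change with the shRNA was -0.22 (adjusted p = 0.26). FABP4 shRNA lowered the chemokine CXCL8 (-2.83, adjusted p = 2.6e-04), whose change with rosiglitazone was -0.05 (adjusted p = 0.94). Both differed between the contrasts (adjusted p = 9.2e-07 for IL6 and 0.0014 for CXCL8). Non-targeting replicates 1 to 3 read 7.65, 9.93 and 8.91 for CXCL8, against 5.82 to 6.14 with the shRNA, so that the size of its fall is not exact.

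The real split of the 6 UM-UC9 arrays, with 4789 genes, was 1 of 10 that gave as many, and the highest other count was 0. In UM-UC14 it was 1 of 10 with 3502 genes against 1, and for the control groups of the lines 1 of 10 with 3449 genes against 0. For genes changed in both contrasts, with the split of the other line kept, it was 1 of 10 with 1547 genes against 1. The limit set beforehand, fewer than 5 of 100 joint splits, was met, but it was badly chosen, since a gene counts only if both lines call it and the joint splits add nothing to the 10 of each line. With 10 splits the share cannot fall below 0.05. For the difference between the contrasts 1 of 100 splits gave 5520 genes, against 3612 at most in the others. Other splits remove part of the treatment effect in 1 or both lines, which favours the real split if either treatment acts. The count thus argues against no effect in either line, but it cannot show that the effects differed between the lines. If the arrays of a group are repeats of 1 culture, chance differences between cultures cannot be excluded.

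Genes changed in both contrasts mostly went in opposite directions (1190 of 1547), and a candidate explanation is a culture state that also varied among the non-targeting replicates. Replicate 1 minus replicates 2 and 3 correlated across genes with the rosiglitazone fold changes, from other arrays, at r = -0.285. The condition against it was an r no larger than that of another split of the UM-UC9 arrays. This condition was set before that r was computed, but it names a replicate and a pattern that only the data could show. It was met (0.304), but it was badly chosen, since other splits keep part of the treatment difference and r takes no account of its size. With the arrays normalized together, the r between the contrasts was -0.0971 against replicate 1 alone (-0.0993 with replicates 2 and 3 left out before normalization) and -0.311 against replicates 2 and 3, while single FABP4 shRNA arrays gave 0.0452 at most in the same comparison with rosiglitazone and single UM-UC9 arrays 0.254 at most with the shRNA fold changes. With the difference of replicate 1 from replicates 2 and 3 regressed out of the rosiglitazone fold changes, their r with the shRNA fold changes was -0.154. FABP4 itself, which the design moved in opposite directions, stays open as an explanation, and this and the culture state cannot be told apart for these genes because the culture conditions of each array are not given in the sources used here.

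Non-targeting replicate 1 lay nearer the FABP4 shRNA arrays than replicates 2 and 3 did. Knockdown cells mixed into it would move FABP4 as far as other genes, but FABP4 lay 11.2% of the way to the shRNA arrays on the linear scale, against a median of 46.1% (quartiles 15.86% and 70.01%) for 304 genes changed at least 2-fold, 71 of which lay below FABP4. Its 21333 detected probes lay within the 20892 to 22407 of the others, which was the condition against a poorer array. Only the array with the fewest detected probes would have failed that condition, so a poorer array is not excluded. TXNIP, which responds to glucose and was chosen after its values were seen, read 10.37 on replicate 1, 7.09 and 7.51 on replicates 2 and 3, and 9.86 to 10.19 with the shRNA. A culture difference may account for this and was not tested directly.

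Interferon genes were lower in both contrasts (with FABP4 shRNA, adjusted p = 0.072 with an estimated correlation) although FABP4 moved in opposite directions. Of 17 members changed in both, 14 fell in both and 3 went opposite ways. FABP4 level acting with the same sign in both lines cannot alone account for the falls of those 14 in both contrasts. Since the 14 are defined by their direction, the counts do not exclude an effect of FABP4 in 1 of the lines, which stays open. Background correction or scaling is argued against, since over both contrasts and 3 other settings the highest list median was -0.36, with median scaling. The other settings, the authors' values and quantile normalization without background correction, hold nearly the same values and are not separate checks. In non-targeting replicate 1 the list median lay -2.84% of the way to the shRNA arrays, under the limit for excluding a culture state. That limit was set before this value was computed, but it names a replicate and a pattern that only the data could show. Of 23 members that fell with the shRNA, however, 13 lay toward those arrays and 10 away from them (quartiles -50.4% and 51.6%). That culture state thus stays open, although the list also fell against replicate 1 alone (median -0.51, adjusted p = 1.3e-08 with the preset correlation), as do untested effects of the drug and of the shRNA that are separate from FABP4.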
